A study of Mus musculus with 12 samples.

How the data were processed

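Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in 12 libraries of P19 cells, a mouse embryonal carcinoma line, in 6 groups of 2 libraries. Per the labels' protocols, cells were infected in medium with 8 µg/ml polybrene, the medium was changed after 24 h, and cells were moved to a neuronal medium after 48 h. Chromatin was fixed in 1% formaldehyde for 11 min and sonicated to fragments of about 150 to 600 bp. The 2 libraries of a group differ in the antibody, so the antibody and the replicate cannot be separated. MyoD antibodies 6196 and 6975 were used for MyoD, the chimera and both of its mutants. NeuroD2 antibodies 1165 and 1240 were used for NeuroD2. Antibodies 1240 and 6975 were used for untransduced cells.

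The data analysed were 5 deposited lists of binding sites, 1 for each transduced group, and the labels of both libraries of a group point to the same list. Per the submitters' processing notes, CASAVA 1.8.2 and BWA 0.7.5 were used and the genome build was mm9. The peak caller, the background, the filters, and whether reads were pooled or calls were merged are not given in the sources used here. Each site has a start, an end and a value. The authors' deposited values were read as −log10 of a p-value from the numbers themselves: all lie above 5, the highest finite value is 312.2, and 59 are given as infinite. No header or label names that unit, so the values were used only to rank sites within a list. Read depth is unknown, and no list of the untransduced cells was analysed here, so no background level can be set beside the shares.

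A site was called bound by another protein where the deposited intervals overlapped by at least 1 base. MyoD-only sites are MyoD sites with no NeuroD2 overlap, NeuroD2-only sites are the converse, and shared sites are MyoD sites with a NeuroD2 overlap. Each single share has an exact Clopper-Pearson interval in the tables. The 95% intervals printed in the text come from resampling 274 genome blocks of 10 Mb with replacement in 1000 draws, and they describe variation along the genome, not between cultures. Overlap expected by chance came from 100 random placements of the sites within the part of each chromosome that the lists span. A share or an overlap index passed the test where it lay above all 100 placements, and a difference or an odds ratio where its 95% interval excluded no difference. No p-value was computed, since each group has 1 list. Overlap of 2 lists was also given as the Jaccard index, the bases in both lists as a percentage of the bases in either.

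The sites and windows named follow a rule that covers the case where no gene can be placed. It takes the 3 sites with the highest value in each class, and in each direction the 3 windows of 100 kb with the largest difference in the number of sites, between MyoD and NeuroD2 and between each chimeric protein and each parent. It also takes the chromosomes with the most and the fewest sites. Sites tied at an infinite value were ordered by width, a choice made after the values were seen. The summary prints all sites of the rule that do not repeat and the leading windows. Coordinates are 1-based in mm9.

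The groups, tests, naming rule and 7 kinds of alternative were fixed before the data were examined. These alternatives were a minimum overlap of 50% of the shorter site, centres at most 100 bases apart, the 50% of each list with the highest values, lists shortened to the length of the shortest, autosomes only, sites within 500 bases joined, and chance overlap from local displacement by 10 to 100 kb. The other 4 were chosen after seeing the data: a common filter of 19 autosomes and widths of 125 to 2000 bases, classes built from the 50% of MyoD and NeuroD2 sites with the highest values, removal of windows of 100 kb with 10 or more sites of any list, and the WC list shortened to the length of the WCS list. The planned results on E-boxes, on Pbx and Meis motifs, on genomic annotation and on gene lists were not run, because they need a genome or annotation of mm9. The gene table used here belongs to GRCm38.p6, so no gene was placed.

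The overlap calculation was tested on simulated data. All 9 simulated class shares, over 49960 sites, came back within 1 percentage point and inside their intervals. Of 10 pairs of lists placed at random, over 119749 sites, 0 lay above all placements. The simulated chimeric lists copied whole sites and the random lists were placed evenly. These simulations therefore covered neither partial overlap nor clustering of sites. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.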

Results

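The binding of MyoD, NeuroD2 and 3 chimeric proteins was mapped by ChIP-seq in mouse P19 embryonal carcinoma cells transduced with each protein. MyoD is the basic helix-loop-helix (bHLH) transcription factor of skeletal muscle, and NeuroD2 is a bHLH factor of neurons. MD(ND2bHLH), called the chimera here, is MyoD in which the bHLH domain, the part that dimerises and contacts DNA, is that of NeuroD2. MD(ND2bHLH)WC and MD(ND2bHLH)WCS, called WC and WCS, are mutants of the chimera, and the labels do not say what their letters stand for. The question the series poses is whether binding site choice sets the lineage a bHLH factor directs. Each of the 5 transduced groups has 2 libraries, made with different antibodies, and 1 list of sites, so no spread between replicates can be given, and the 95% intervals come from resampling genome blocks. The 2 untransduced libraries served the submitters as negative controls, and no list of theirs was analysed here.

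MyoD bound 24935 sites and NeuroD2 31458 sites. The chimera bound 14375 sites, the fewest of the 5 lists, WC bound 27045 and WCS 22462. The lists covered 9.94 Mb for MyoD, 12.1 Mb for NeuroD2, 7.36 Mb for the chimera, 10.3 Mb for WC and 8.10 Mb for WCS. Median site width was 358 bp for MyoD, 341 bp for NeuroD2, 431 bp for the chimera, 349 bp for WC and 329 bp for WCS. Chromosome 2 held the most sites in every list, with 2288 MyoD and 2592 NeuroD2 sites. Among the autosomes the fewest sites lay on chromosome 16 for MyoD, with 739, and on chromosome 19 for the other 4 lists. Read depth is unknown, so the number of sites is not a measure of binding strength. The lists of MyoD and the chimera held 0 sites on chromosome X and none shorter than 125 bp, whereas NeuroD2 had 570 sites on X, WC 403 and WCS 362, with shortest sites of 53, 54 and 54 bp.

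The MyoD and NeuroD2 lists held largely different sites in the same cell type. They also differ in antibodies and may differ in batch or filters, which cannot be told apart from the protein. Of the MyoD sites, 6420 or 25.7% overlapped a NeuroD2 site (95% interval 24.9 to 26.5%), and 20.4% of NeuroD2 sites overlapped a MyoD site (19.5 to 21.3%). Random placement gave 1.04% and 0.827% and local displacement 2.13% and 1.69%, so both shares exceeded chance. This left 18515 MyoD-only sites, 6420 shared sites and 25034 NeuroD2-only sites. Shared sites had the higher values in the MyoD list, with a median of 15.1 on the authors' scale against 9.74 for MyoD-only sites.

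Of the 8 MyoD-only sites with an infinite value in the MyoD list, the 3 widest were chromosome 15 from 103000056 to 103001018, chromosome 4 from 134356374 to 134357204 and chromosome 6 from 115073011 to 115073784 (mm9). The chimera bound all 3, WC bound the sites on chromosomes 15 and 6, and WCS bound only the site on chromosome 15. The shared sites with the highest values in the MyoD list lay on chromosome 17 from 25792759 to 25793594, chromosome 8 from 125374491 to 125375094 and chromosome 9 from 62013887 to 62014381. Their values in the NeuroD2 list were 6.46, 16.4 and 22.5. The site on chromosome 17 was bound by the chimera and by neither mutant, and the other 2 were in all 5 lists. The 3 NeuroD2-only sites that led the class, at an infinite value shared by 31 sites, lay on chromosome 9 from 3024474 to 3027974 and from 3021932 to 3023919, and on chromosome 15 from 74915805 to 74917630, and no other list held them. Whether reads map uniquely at these sites was not tested.

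Clusters of sites also differed between both parents. MyoD had most over NeuroD2 in windows of 100 kb that start at 60800001 on chromosome 11, with 14 MyoD and 4 NeuroD2 sites, at 117700001 on chromosome 11, with 13 and 3, and at 78600001 on chromosome 15, with 13 and 3. Windows from 13100001 on chromosome 8, with 12 and 2, and from 45300001 on chromosome 19, with 11 and 1, tied with them. The largest excess of NeuroD2 was far greater: 74 NeuroD2 and 3 MyoD sites from 19900001 on chromosome 8, 69 and 5 from 19700001 on chromosome 8, and 66 and 5 from 14900001 on chromosome 5. In these 3 windows WC had 42, 63 and 62 sites, WCS 47, 64 and 59, and the chimera 7, 9 and 10. The lists with many sites there are those that hold chromosome X and short sites, so a difference in filters cannot be told apart from the protein. Whether reads map uniquely in these windows was not tested.

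The lists of the mutants resembled that of NeuroD2, and the chimera's list lay between those of both parents. NeuroD2, WC and WCS are also the lists that hold chromosome X and short sites. The set of lists therefore cannot be told apart from the protein here. The Jaccard index was 41.5% for NeuroD2 and WC (40.5 to 42.4%) and 40.1% for NeuroD2 and WCS (39.0 to 41.1%), against 17.2% for NeuroD2 and the chimera (16.5 to 17.9%). With MyoD the order was the opposite, at 25.1% for the chimera (24.7 to 25.6%), 13.6% for WC (13.1 to 14.1%) and 12.8% for WCS (12.3 to 13.3%). WC and WCS had the highest index of the 10 pairs, 55.3% (54.2 to 56.5%), and MyoD and NeuroD2 the lowest, 10.8% (10.4 to 11.2%). The chimera overlapped WC at 23.9% and WCS at 22.4%. All 10 pairs exceeded random placement, which reached at most 0.287% for NeuroD2 and WC.

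**Figure D1:**
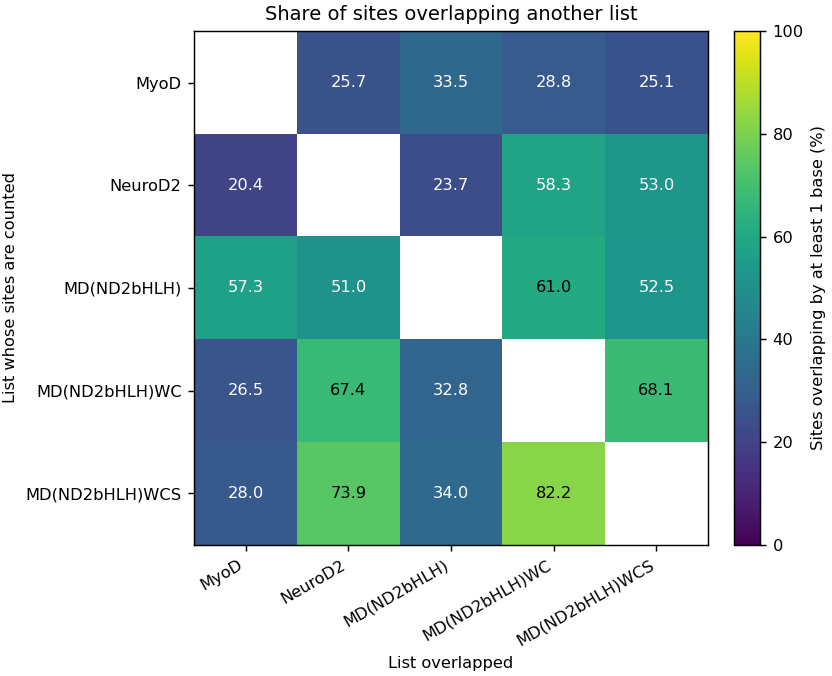
Share of the sites of each list (rows, in percent) that overlap a site of another list (columns) by at least 1 base. Of the WCS sites 82.2% overlapped WC and 73.9% NeuroD2, while 28.0% overlapped MyoD. Of the chimera sites 57.3% overlapped MyoD and 51.0% NeuroD2.

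The chimera bound sites of both parents, with a larger share of the MyoD-only than of the NeuroD2-only class. The chimera bound 65.6% of shared sites (64.4 to 66.9%), 22.4% of MyoD-only sites (21.7 to 23.0%) and 12.9% of NeuroD2-only sites (12.2 to 13.6%), all above random placement, which gave at most 0.872%. The odds of being bound were lower for NeuroD2-only than for MyoD-only sites, with an odds ratio of 0.515 (0.480 to 0.552). Of the chimera's own sites 29.1% overlapped both parents, 28.1% MyoD alone, 21.9% NeuroD2 alone and 20.9% neither. With all lists shortened to 14375 sites the chimera held 36.7% of MyoD-only and 23.2% of NeuroD2-only sites, 15.2% of its sites overlapped both parents and 36.4% neither. MyoD, the chimera and both mutants were precipitated with the same antibodies and NeuroD2 with others, and a batch common to the MyoD and chimera lists cannot be told apart from the protein.

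Both mutants bound mostly shared and NeuroD2-only sites. WC bound 52.3% of NeuroD2-only sites (51.2 to 53.4%), 81.9% of shared sites (81.0 to 83.0%) and 10.3% of MyoD-only sites (9.88 to 10.8%), an odds ratio of 9.53 for NeuroD2-only against MyoD-only sites (8.95 to 10.1). WCS bound 46.8% of NeuroD2-only sites (45.6 to 47.9%), 77.3% of shared sites (76.3 to 78.3%) and 7.06% of MyoD-only sites (6.67 to 7.47%), an odds ratio of 11.6 (10.7 to 12.4). All 6 shares lay above random placement, which gave at most 1.21%.

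**Figure D2:**
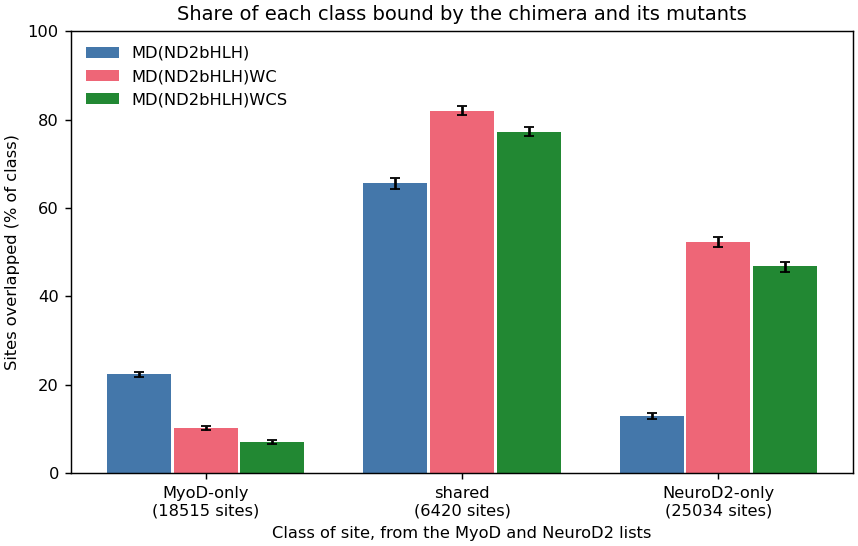
Share of MyoD-only, shared and NeuroD2-only sites (horizontal axis) overlapped by the chimera, WC and WCS, in percent of the class (vertical axis). Bars give the share and whiskers the 95% interval from genome blocks. The chimera bound 22.4% of MyoD-only and 12.9% of NeuroD2-only sites, and WC bound 10.3% and 52.3%.

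Compared site by site with the chimera, the mutants lost MyoD-only sites and gained NeuroD2-only sites. WC held 39.4 percentage points more of the NeuroD2-only class (38.4 to 40.5), with 10182 sites gained and 323 lost, and its share of the MyoD-only class fell by 12.0 points (−12.6 to −11.5), with 734 gained and 2964 lost. WCS held 33.9 points more of the NeuroD2-only class (32.9 to 34.9), and its share of the MyoD-only class fell by 15.3 points (−15.9 to −14.7). In the shared class WC was 16.4 points above the chimera (15.2 to 17.7) and WCS 11.7 points above it (10.5 to 13.0). With lists of equal length these gains in the shared class were 3.01 points for WC and 3.05 for WCS, and the losses of MyoD-only sites were −26.3 and −27.1 points. The chimera's list belongs with MyoD's in lacking chromosome X and short sites and the mutants' lists belong with NeuroD2's, so the set of lists and the mutation cannot be told apart in this comparison.

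Most of the NeuroD2-only sites in the chimera's list were also in the mutants' lists, and most of its MyoD-only sites were not. Here too the set of lists and the mutation cannot be told apart. Of the 3234 NeuroD2-only sites bound by the chimera, WC held 90.0% (88.9 to 91.1%) and WCS 84.9% (83.5 to 86.4%). Of the 4141 MyoD-only sites bound by the chimera, WC held 28.4% (26.9 to 30.02%) and WCS 17.3% (16.0 to 18.6%). Among the NeuroD2-only sites outside the chimera's list, 46.7% were in the WC list (45.6 to 47.8%) and 41.2% in the WCS list (40.0 to 42.2%).

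The chimera sites of highest value that WC lacked were all MyoD sites. They lay on chromosome 7 from 19876615 to 19877022, with a value of 175.4 in the chimera list, on chromosome 11 from 94335497 to 94336135 and on chromosome 17 from 8199463 to 8200011. WCS lacked the same site on chromosome 7, as well as chromosome 6 from 115073201 to 115073775 and chromosome 3 from 88433852 to 88434455, both of which WC held. The sites gained with the highest values were common to WC and WCS. They lay on chromosome 2 from 181747330 to 181748052 and on chromosome 9 from 3006602 to 3007048 and from 3003308 to 3003690, in a window of 100 kb that held 29 NeuroD2 sites. Each mutant gained 4 sites at an infinite value, of which these are the 3 widest. The MyoD and chimera lists lack them and may have had other filters. How uniquely reads map in these places was not tested.

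The share of sites bound rose with the authors' value of the site in every class. Each class was divided into 5 equal bins by value, that of the MyoD list for MyoD-only and shared sites and that of the NeuroD2 list for NeuroD2-only sites. From bin 1, the lowest, to bin 5, the highest, the share of NeuroD2-only sites bound rose from 26.3% to 86.3% for WC, from 22.1% to 81.5% for WCS and from 5.77% to 27.6% for the chimera. For MyoD-only sites it rose from 9.45% to 47.4% for the chimera, from 5.37% to 18.9% for WC and from 4.29% to 10.6% for WCS. In bin 5 of the shared class, the sites of highest MyoD value, the chimera and WC bound nearly equal shares, 91.3% (89.7 to 92.8%) and 91.6% (90.2 to 93.0%), against 45.1% and 75.5% in bin 1, while WCS bound 86.7% (84.9 to 88.3%) in bin 5 and 70.1% in bin 1.

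**Figure D3:**
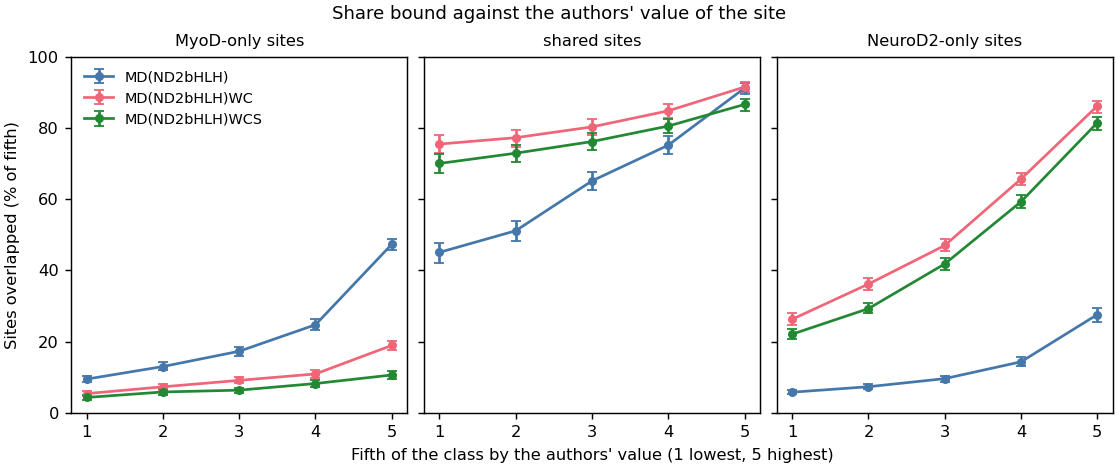
Share of sites overlapped by the chimera, WC and WCS (vertical axis, percent) in 5 bins of each class by the authors' value in the MyoD list, or in the NeuroD2 list for NeuroD2-only sites (horizontal axis, 1 lowest, 5 highest), with 95% intervals from genome blocks. In bin 5 of the NeuroD2-only class WC bound 86.3% and the chimera 27.6%, and in bin 5 of the MyoD-only class WC bound 18.9% and the chimera 47.4%.

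WCS bound a smaller share of every class than WC, whose list is longer. The differences, WCS minus WC, were −3.26 points for MyoD-only sites (−3.63 to −2.85), −4.63 for shared sites (−5.61 to −3.70) and −5.48 for NeuroD2-only sites (−6.01 to −4.98). With the WC list shortened to the 22462 sites of WCS, an alternative chosen after seeing the data, the difference was −0.783 points for MyoD-only sites (−1.14 to −0.339), 0.592 for shared sites (−0.321 to 1.55) and 0.731 for NeuroD2-only sites (0.172 to 1.35). The log2 odds ratio of NeuroD2-only against MyoD-only sites was higher in WCS than in WC by 0.28 (0.19 to 0.36), by 0.16 (0.06 to 0.26) with all lists of equal length and by 0.21 (0.11 to 0.30) with the shortened WC list.

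Some sites of the 3 chimeric proteins were bound by neither parent. These made up 20.9% of the chimera list (2998 sites), 25.5% of the WC list (6906 sites) and 20.2% of the WCS list (4530 sites). Their median values were low, 7.41, 7.36 and 6.74 on the authors' scale. Of the 4530 such WCS sites 56.9% were also in the WC list and 11.4% in the chimera list. The sites of highest value held by the chimera alone lay on chromosome 7 from 31834841 to 31835292, with a value of 91.6, on chromosome 13 from 58087963 to 58088408, with 81.9, and on chromosome 10 from 61391458 to 61392292, with 73.3. The order of these shares depended on the setting. Where site centres had to lie within 100 bases, the share bound by neither parent was 33.3% for the chimera, 30.9% for WC and 25.99% for WCS. With lists of equal length it was 36.4%, 30.1% and 29.9%, so both settings put the chimera first. Equal length cuts the other lists by value and leaves the chimera list whole. The rule on centres makes no allowance for width, and chimera sites had the largest median width, 431 bp. Neither setting decides the order. With the 50% of each list of highest value, WC stayed first, at 27.4% against 23.8% for the chimera and 21.8% for WCS. WC was also first in the other alternatives that covered these shares, but only at 21.0% against 20.9% with its own list shortened.

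Merged over all lists, the sites formed 60136 regions, of which 31379 were in a single list and 3515 in all 5. The largest groups of regions held by more than 1 list were the 7602 regions of NeuroD2, WC and WCS without MyoD or the chimera, and the 3515 regions of all 5 lists. A further 2643 regions were in the MyoD and chimera lists alone, and 2599 were in every list except MyoD's. MyoD alone held 13371 regions and NeuroD2 alone 10412.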

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

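The tests of the 2 sets of lists, of the common filter, of the shortened WC list and of list length for NeuroD2-only sites were chosen after the result they bear on was seen.

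The preference for NeuroD2-only over MyoD-only sites differed between the chimera and its mutants, with a log2 odds ratio 4.21 higher in WC (4.10 to 4.32) and 4.49 higher in WCS (4.38 to 4.61), by a test of the difference itself on the same sites. The listed sites on chromosome X and those outside widths of 125 to 2000 bases do not account for it. With 19 autosomes and those widths the gap between WC and the chimera was 4.17 (4.06 to 4.27). That filter left 26599 of 27045 WC sites and 14355 of 14375 chimera sites. It cannot restore sites that earlier filters may have removed, so it does not decide whether filters differed. The shortest chimera site had 200 bp, a floor that was not applied to the other lists. The short chimera list does not account for it either, since the gap was 4.43 (4.30 to 4.57) with lists of equal length. A batch that joined the NeuroD2, WC and WCS lists cannot be told apart from the mutations: the split of MyoD and the chimera against the other 3 lists held 10245 regions, the most of the 10 splits, against 2564 in the next, which both explanations predict. A change in binding preference caused by the mutations may underlie the gap, and it stays a hypothesis while the sets of lists coincide with the groups.

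The odds ratio also differed between the WC and WCS lists, which belong to the same set. The gap was 0.28 on the log2 scale (0.19 to 0.36), or 0.16 (0.06 to 0.26) with all lists of equal length. These intervals describe variation along the genome. Whether libraries of the same protein differ by as much was not tested. For NeuroD2-only sites the lower share of WCS went with list length. WC minus WCS was −0.540 points (−1.19 to 0.151) with all lists of equal length and −0.731 points (−1.35 to −0.172) with the WC list alone shortened. Shortening also removes any real difference in the number of sites bound, so it cannot tell why the WCS list is shorter. For MyoD-only sites most of the difference went with length too, but 0.815 points (0.239 to 1.38) remained with all lists of equal length and 0.783 points (0.339 to 1.14) with the WC list shortened. Narrower WCS sites do not account for the whole MyoD-only difference of the full lists. It was 2.72 points (2.33 to 3.09) where centres had to lie within 100 bases. Width and length were not equalised together, so width stays open for the remainder after shortening. A somewhat weaker hold of WCS on MyoD-only sites stays open as a hypothesis, and the depth of both libraries, which is unknown, was not tested.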

How the results depend on the processing

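The common filter, the classes from high-valued sites, the removal of crowded windows and the shortened WC list were chosen after seeing the data. Local displacement covered 21 results, the classes from high-valued sites 24 and the shortened WC list 21, against up to 53 for the other alternatives. All results with a test but 2 kept their direction and their side of the test under every alternative that covered them. The 2 were the WCS minus WC differences in the shared and NeuroD2-only classes. With all lists of equal length these were 0.0368 (−1.03 to 1.10) and 0.540 points, and with the WC list shortened 0.592 and 0.731 points. Both alternatives leave fewer WC sites by construction, so they cannot tell list length from a real difference in binding. The log2 odds ratio ranged over the alternatives from −1.17 to −0.92 for the chimera, from 3.15 to 3.98 for WC and from 3.40 to 4.32 for WCS. Local displacement gave higher chance shares than random placement, 2.45% against 0.865% for WC on NeuroD2-only sites and at most 2.90% in any class. The share of MyoD sites bound by NeuroD2 ranged from 18.9% to 26.3%. Where overlap was defined by 50% of the shorter site or by centres, the overlap index counted sites in place of bases. With an overlap of 50%, autosomes only, local displacement, the common filter or the classes from high-valued sites, 0 results moved, although the last changed 6 values by over 1.5 times without a change of direction. Numbers of sites included, 16 values changed by over 1.5 times with lists of equal length and 5 with the 50% of highest value. The shortened WC list changed 3 and centres within 100 bases 2. With lists of equal length, WC minus the chimera in the shared class was 3.01 points in place of 16.4.

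Numbers of sites changed by construction, to 12467 for MyoD, 15729 for NeuroD2, 7187 for the chimera, 13522 for WC and 11231 for WCS with the 50% of highest value, and to 14375 for MyoD, NeuroD2, WC and WCS with lists of equal length. The make-up of the 3 chimeric lists also moved. With centres within 100 bases, sites bound by neither parent were 33.3% for the chimera, 30.9% for WC and 25.99% for WCS, by both parents 19.3%, 14.5% and 16.6%, by NeuroD2 alone 19.9% for the chimera and by MyoD alone 6.75% for WC. With the 50% of highest value, neither was 23.8%, 27.4% and 21.8% in that order, both 23.9%, 16.0% and 18.3%, MyoD alone 31.0%, 6.65% and 5.48%, and NeuroD2 alone 49.9% for WC and 54.4% for WCS. With lists of equal length, neither was 36.4%, 30.1% and 29.9%, both 15.2%, 15.8% and 15.8%, MyoD alone 29.6%, 8.43% and 7.86%, and NeuroD2 alone 18.8%, 45.7% and 46.4%. With sites joined, both was 20.02% for WC and 22.7% for WCS. Without crowded windows, neither was 21.8% for the chimera and 26.1% for WC, both 27.9%, 18.7% and 21.4%, and MyoD alone 29.1% for the chimera. With the WC list shortened, its sites were 21.0% neither, 21.8% both, 6.46% MyoD alone and 50.7% NeuroD2 alone. Fewer parent sites are left to overlap with the 50% of highest value and with lists of equal length, but the shortened WC list left both parent lists unchanged. The cause of these moves was not tested.

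No paired analysis was possible because each group has 1 list over both libraries, and for the same reason no library could be left out. Alternatives for E-boxes, Pbx and Meis motifs, annotation and gene lists were not run. Depth is unknown, so a site missing from a list may be a site below detection. Lists of equal length leave the chimera list unchanged and do not correct for its depth. The chimera held 23.2% of NeuroD2-only sites there in place of 12.9%, with the classes redrawn from shortened MyoD and NeuroD2 lists.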

Other observations

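The tests of neighbourhoods and of value ranks were added to the plan before their results were seen. The threshold for crowded windows and the test of adjacent sites were chosen after the counts or shares were seen.

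Some regions were taken up by the mutants without either parent or the chimera. WC and WCS alone shared 2151 regions. Windows of 100 kb were ranked by the excess of WC and WCS over NeuroD2, so MyoD and the chimera may have sites there. One lay on chromosome 10 from 77200001, where WC had 17 sites, WCS 18, the chimera 15, MyoD 11 and NeuroD2 4. Another lay on chromosome 14 from 44000001, where WC had 13, WCS 15, the chimera 2 and each parent 1. NeuroD2 in turn had clusters with few sites in the other lists, with 62 sites from 90100001 on chromosome 1 against 5 or fewer in each other list, and 38 from 173400001 on chromosome 1 against 3 or fewer. MyoD had 12 sites from 13100001 on chromosome 8, where NeuroD2 had 2, WCS 1 and the chimera and WC 0.

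Windows with 10 or more sites numbered 188 for NeuroD2, 103 for MyoD, 96 for WC, 70 for WCS and 15 for the chimera, numbers that depend on the length of each list. Windows crowded in at least 1 list held 10.8% of NeuroD2 sites, 7.58% of MyoD, 9.14% of chimera, 9.41% of WC and 10.5% of WCS sites. Of the 34 NeuroD2 sites with an infinite value, 18 lay in windows crowded in at least 1 list. A window from 15100001 on chromosome 5 held 59 NeuroD2, 54 WC and 58 WCS sites, against 8 for the chimera and 0 for MyoD. Unique mapping of reads in crowded windows was not tested, and filters may differ between the sets of lists.

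At the 3515 regions in all 5 lists, the authors' values ranked most alike in WC and WCS (Spearman's rho 0.793 across regions, which are not independent replicates) and in NeuroD2 and WCS (0.683) or WC (0.666). MyoD and NeuroD2 ranked these regions almost independently (0.0709, 95% interval 0.0372 to 0.105). The hypothesis that the chimera's values follow MyoD's more than NeuroD2's was tested by the difference of both correlations, 0.125 (0.0876 to 0.161), which is consistent with it. The chimera's correlation with WC was higher (0.512, 0.487 to 0.537) than with MyoD (0.411, 0.383 to 0.438). With WCS it was not (0.386, 0.355 to 0.416). WC and WCS both belong to the other set of lists, and neither difference from MyoD was tested.

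MyoD-only and NeuroD2-only sites were found within 10 kb of each other somewhat more often than local displacement gave, for 27.7% of MyoD-only sites against 25.3 to 26.8% over 100 displacements by 10 to 100 kb. Within 500 bases the order was the opposite, 0.621% against a mean of 1.79% over displacements, where the definition of MyoD-only sites removes overlaps that displaced sites may have. Splitting of regions of up to 2000 bases into adjacent sites does not account for the excess, since 22.6% of the 17285 sites with no NeuroD2-only site within 2000 bases had one within 10 kb, against 20.2 to 21.3% over displacements held to the same condition and to no overlap with NeuroD2, while wider regions stay open. Both factors may therefore use different sites in the same neighbourhoods, a hypothesis that rests on a small excess. Chromatin accessibility, which would draw both factors to the same neighbourhoods, was not tested.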
